A study of Saccharomyces cerevisiae with 42 samples.

How the data were processed

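Gene expression was measured in yeast strains HOG1-GFP, hog1del and HOG1-CCAAX before and 60 min after 1 M sorbitol at 25 C, with 3 biological replicates of each of the 6 groups. Per the labels, RNA was amplified with amino-allyl nucleotides, the sample was labelled with Cy3 and a common reference pool with Cy5, and replicate 1 was read as technical triplicates whereas replicates 2 and 3 were read as duplicate features within a slide. The deposited values of the 42 array columns are log2 ratios of sample over reference, as the direction of known osmotic genes and of HOG1 in hog1del shows. The scanner, background correction and normalization are not stated in the labels. The authors also deposited log2 values averaged over technical replicates, the differences of 60 min minus 0 min, and those differences for 30 chosen genes, all with the opposite sign (reference over sample), so they were turned before use. The authors' averages had a correlation of at least 0.997 with the means computed here.

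The value table held 8623 features, 6267 of them with the name of an open reading frame (ORF), of which 5795 matched a gene of the R64 reference annotation and 472 did not. The other 2356 features were not tested. Each array was centred on its median, the technical replicates were averaged, and the 5487 genes with a value in all 18 biological samples were tested. Of these, 5229 had a position in the reference, and the rest, such as YBR116C, were counted as genes too. The median response over all genes lay within 0.037 of 0 in every strain and replicate, and within 0.067 without centring. Each array gave 5221 to 6075 ORF values. The 3 replicates per group, of which replicate 1 correlated poorly with the others, limit the precision. Genes with no value after this filter, such as GPD1, GPP1, GPP2, HSP12, GRE2 and PRM1, are given separately or not reported.

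limma 3.58.1 in R 4.3.3 fitted the 9 responses (60 min minus 0 min within a strain and replicate) with the strain as the group, 6 residual degrees of freedom and empirical Bayes moderation, for the mean response of each strain and the differences between strains. Levels before sorbitol were compared in a fit of all 18 biological samples with the replicate as a block, with 10 residual degrees of freedom. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The gene lists were fixed in advance, and the 26 lists with at least 5 measured members and meant for testing were tested with camera at an inter-gene correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the 26 lists within each comparison. Members were also adjusted over the list alone. The mean response of the authors' 30 genes per replicate was compared by a two-sided exact permutation test. Tables and figures were made with Python 3.11, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

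The genes named in the text were set by a rule. For each comparison it took the 8 largest increases and 6 largest decreases among called genes that moved alike in all replicates (for differences between strains in response, with no overlap between the replicates of the strains, which chance gives 10% of genes for 3 against 3), 2 members of each list that passed camera, and a fixed set of osmotic and mating genes, with HOG1 and the extremes of the authors' genes in HOG1-CCAAX. Other names are said to be chosen after their values were seen.

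Whether the replicate numbers pair the strains was checked from the correlation of deviations from the group means. Responses with the same number had a correlation of 0.438 to 0.816, and levels of at least 0.172. These correlations come from replicate 1 against replicates 2 and 3, since within replicates 2 and 3 alone the correlation was -0.299 to 0.115. No pairing of the strains within replicates 2 and 3 was therefore shown. The block, which takes up the gap between replicate 1 and the others, was fitted as an alternative for the strain differences. Of the 9 responses, 6 correlated best with their own number, which that gap can give without any pairing of replicates 2 and 3.

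The alternatives were no centring, quantile normalization, genes measured in at least 2 of 3 replicates (6006 genes), technical replicate 1 only (4907 genes), technical replicates kept with the biological sample as a random block (consensus correlation 0.662), the authors' averaged tables (5434 genes), robust empirical Bayes, a 2-fold minimum, each replicate left out, and fits with and without the replicate block. The fits were tested on simulated data with 200 changed genes among 5487. For the difference of hog1del from HOG1-GFP in response, 50% of changes of log2 1 and 86% of log2 2 were recovered with 7 unchanged genes called, and for the level difference before sorbitol 84% and 100% with 11. In the simulated lists, camera called 1 of 1 shifted list and 0 unchanged lists. The simulated noise was drawn for each gene on its own, and for the responses and lists without any effect shared within a replicate. The simulation therefore cannot show whether the preset correlation of camera holds for the real lists. Nor does it show how many changes are recovered when genes or replicates share such effects.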

Results

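Messenger RNA of budding yeast was measured on 2-colour arrays in 3 strains, before and 60 min after a shift to 1 M sorbitol, which raises the osmotic strength of the medium. HOG1-GFP carries the osmotic stress kinase Hog1 joined to green fluorescent protein, hog1del lacks the HOG1 gene, and HOG1-CCAAX carries Hog1 with a motif that tethers proteins to membranes. A probe for green fluorescent protein gave a signal in HOG1-CCAAX too, as given below. Each of the 6 groups held 3 biological replicates, which gave 18 biological samples. Replicate 1 gave 18 deposited sets of array values with 5693 to 5899 genes each, replicate 2 gave 12 with 5826 to 6074, and replicate 3 gave 12 with 5221 to 6075. Technical replicates of a sample had a correlation of 0.385 to 0.976 in replicate 1. It was at least 0.965 in replicates 2 and 3, where they are duplicate features within a slide. Between biological replicates of a group, the correlation was 0.309 to 0.574 for replicate 1 with the others, and 0.92 to 0.969 between replicates 2 and 3. The responses below are log2 ratios of 60 min over 0 min within a strain and replicate, given as mean ± SE of the fit (n = 3 replicates) for the 5487 genes measured in every biological sample. This SE comes from limma, which pools the spread of a gene over all strains and moderates it. It is therefore not the spread of the named strain alone. The SDs of STL1, for example, were 0.53, 0.72 and 0.24 in HOG1-GFP, hog1del and HOG1-CCAAX, while its SE is the same in each. The precision is limited by n = 3 and by replicate 1, which correlated poorly with the others. Without replicate 1, the genes called for the response of hog1del minus that of HOG1-GFP rose from 149 to 1083.

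The HOG1 transcript was read first, since it checks the strain labels. Its log2 ratio to the reference pool was -0.08 ± 0.05 (SD, n = 3) before sorbitol and 0.33 ± 0.12 after it in HOG1-GFP, and -0.26 ± 0.10 and 0.28 ± 0.26 in HOG1-CCAAX. In hog1del it was -3.23 ± 0.21 before and -3.70 ± 0.26 after, so every hog1del sample lay below every sample of the other strains.

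**Figure D1:**
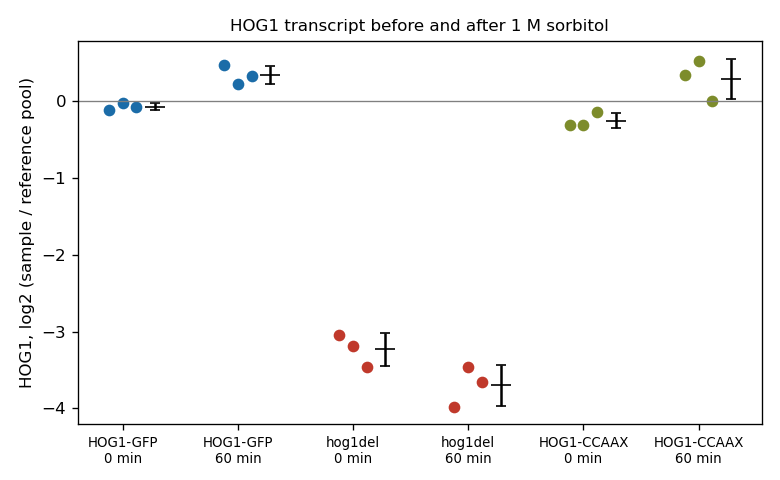
HOG1 transcript level per biological replicate (log2 ratio to the reference pool, vertical axis) in the 3 strains before and 60 min after 1 M sorbitol, with bars at the means. The hog1del samples lie between -3.98 and -3.04, and all other samples between -0.32 and 0.52.

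The first comparison asked how cells with Hog1-GFP respond to sorbitol. The largest increases were in MPC3, a subunit of the mitochondrial pyruvate carrier (5.74 ± 0.27), the aldehyde dehydrogenase ALD3 (5.19 ± 0.36), YBR116C (5.12 ± 0.30), the glycerol importer STL1 (4.85 ± 0.27) and the catalase CTT1 (4.73 ± 0.27). TKL2 and NQM1, a transketolase and a transaldolase of the pentose phosphate pathway, rose by 4.63 ± 0.50 and 4.69 ± 0.23. The largest decreases were in the phosphate transporter PHO84 (-4.20 ± 0.15), the purine salvage enzyme HPT1 (-3.06 ± 0.15), the ribosome assembly factor NOP7 (-3.04 ± 0.50), YDL241W (-2.93 ± 0.24) and the acid phosphatases PHO11 and PHO12 (-2.86 ± 0.17 and -2.85 ± 0.15).

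Of 25 measured osmotic stress genes listed in advance as needing Hog1, 24 rose and 1 did not pass, with the kinase FMP48 at 4.20 and YML131W at 3.99 as examples. The median of that list was 3.60. Of 38 targets of the general stress factors Msn2 and Msn4, 31 rose, 1 fell and 6 did not pass, with MSC1 at 3.80. Of 19 genes of trehalose and glycogen metabolism, 11 rose and 1 fell, among the former UGP1 (1.75) and PIG2 (0.87). Of 30 proteasome genes, 18 rose and none fell, with RPT3 at 1.05 and PRE7 at 0.86, and of 28 oxidative stress defence genes 13 rose and 5 fell. Of 108 cytosolic ribosomal protein genes, whose near-identical copies are uncertain, 95 fell and none rose, with RPL20A at -2.20 and RPS26A at -1.74. Of 78 ribosome biogenesis genes, 69 fell, with RPF2 at -2.59 and LTV1 at -1.73, and of 19 genes of RNA polymerases I and III 12 fell, with RPC40 at -1.61. Of 22 genes of the G2/M and M/G1 phases of the cell cycle, 15 fell, with AMN1 at -2.33 and SCW11 at -1.90. Of 15 genes of the phosphate regulon, 10 fell and 2 rose. Adjusted over the list alone, the counts that rose and fell were 24 and 0 for the osmotic list, 32 and 1 for the Msn2/Msn4 list, 0 and 100 for the ribosomal proteins, 0 and 74 for ribosome biogenesis and 2 and 11 for the phosphate regulon. They were 13 and 1 for trehalose and glycogen, 19 and 0 for the proteasome, 13 and 5 for oxidative stress defence, 0 and 14 for the RNA polymerases and 0 and 16 for G2/M and M/G1. The glycerol synthesis and transport list had 10 measured members, of which 4 rose, also when adjusted over the list alone. Its median of 0.06 and mean of 1.11 lay far apart, and the list did not pass (camera, adjusted p = 0.124).

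limma called 2561 of the 5487 genes in HOG1-GFP, 1306 up and 1255 down. Of these, 2547 had the same sign in replicate 1 as in the mean of replicates 2 and 3. Genes and lists were called on these same replicates, so such agreement in sign, here and in each comparison below, is no independent support. The count was 1176 without replicate 2 and 1091 without replicate 3. The 10 lists named in the counts above, the glycerol list aside, passed camera at its preset correlation, with adjusted p from 1.14e-22 for the ribosomal proteins to 0.0431 for oxidative stress defence. None of the 26 lists passed in camera with an estimated correlation, where the 10 lists had an adjusted p = 0.136 to an adjusted p = 0.565, while 3 lists had an unadjusted p under 0.05 there and 19 passed in fry. fry tests whether the genes of a list move, on balance, one way, and does not compare the list with other genes.

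In hog1del cells, the strain without Hog1, sorbitol still raised CYB2, a lactate dehydrogenase (4.27 ± 0.21), SUE1 (4.23 ± 0.26), MPC3 (3.82 ± 0.27), CTT1 (3.76 ± 0.27) and the arginase CAR1 (3.67 ± 0.23). STL1 had a response of -0.45 ± 0.27 that did not pass (adjusted p = 0.183) but did with quantile normalization (-0.96, adjusted p = 0.0047). The mating genes FUS1, needed for cell fusion, KAR4, a transcription factor of nuclear fusion, and PCL2, a cyclin, rose by 3.41 ± 0.67, 3.13 ± 0.20 and 3.06 ± 0.12. The call of FUS1 was lost without replicate 2 (adjusted p = 0.0622) and without replicate 3 (adjusted p = 0.0599). PHO84 fell by 3.86 and HPT1 by 3.44 on the log2 scale.

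Of 30 measured pheromone response and mating genes, 24 rose in hog1del and none fell, with a list median of 1.65. In HOG1-GFP, limma called 16 of these 30, with 11 up and 5 down at an unadjusted p under 0.05. The list did not pass camera there. Of 6 markers of alpha cells, the other mating type, 5 rose in hog1del and 2 in each other strain, and none differed between the strains in limma, with 0 at an unadjusted p under 0.05. With the replicate as a block, MF(ALPHA)1 responded more in hog1del than in HOG1-GFP. TEC1, a transcription factor shared with filamentous growth, was at 2.84 ± 0.15, and AGA1, an anchor of the mating agglutinin, at 2.05 ± 0.26. Of 25 osmotic stress genes, 19 rose and none fell, with a median of 1.51. Most of this list, drawn up as genes that need Hog1, thus still rose without it. Of 38 Msn2/Msn4 targets 25 rose. Of 21 ergosterol synthesis genes, 11 rose and 1 fell, with ERG5 at 2.33 and ERG6 at 1.02. Of 15 TCA cycle genes, 9 rose, with LSC2 at 1.30. Of 6 core histone genes, 5 fell, with HTA2 at -1.75 and HTA1 at -1.59. Of 108 ribosomal protein genes 94 fell, of 78 ribosome biogenesis genes 66 fell, with NSR1 at -2.37, and of 15 phosphate regulon genes 11 fell and 2 rose. Adjusted over the list alone, 25 mating, 19 osmotic, 28 Msn2/Msn4 and 9 TCA cycle genes rose, 12 ergosterol genes rose and 1 fell, and 6 histone, 101 ribosomal protein, 68 ribosome biogenesis and 11 phosphate regulon genes fell, while 2 of the last list rose.

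limma called 2907 genes in hog1del, 1398 up and 1509 down, of which 2865 had the same sign in replicate 1 as in replicates 2 and 3. The count was 1328 without replicate 2 and 1197 without replicate 3. Of 26 lists 12 passed camera, among them mating (adjusted p = 3.06e-09), ergosterol synthesis (0.00103), the TCA cycle (0.00565) and histones (0.00962). Only the mating list passed with an estimated correlation (adjusted p = 0.0324 with an estimated correlation), while the other 11 had an adjusted p from 0.0712 to 0.642 there. In fry, 19 lists passed. The proteasome list was among the 12 (adjusted p = 0.017), with 9 members up and 7 when adjusted over the list alone, but its median was -0.03 in replicate 1 and 0.55 in replicates 2 and 3.

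In HOG1-CCAAX cells, which hold the membrane-tethered kinase, the largest increases were MPC3 (5.05 ± 0.27), CYB2 (4.58 ± 0.21), CTT1 (4.58 ± 0.27), SUE1 (4.35 ± 0.26) and SPG4 (4.35 ± 0.22). STL1 had a response of 0.69 ± 0.27 that did not pass (adjusted p = 0.053) but did without replicate 1 (0.79, adjusted p = 0.000755), without centring (0.74, 0.0398) and in the fit of 18 samples with the replicate block (0.0393). PHO84 (-3.93 ± 0.15), HPT1 (-3.52 ± 0.15) and the ribosome assembly factors RPF2 and BRX1 (-3.28 ± 0.20 and -3.01 ± 0.19) fell.

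Of 25 osmotic stress genes, 21 rose in HOG1-CCAAX and none fell, with a median of 2.35. Of 38 Msn2/Msn4 targets 31 rose and none fell, and of 19 trehalose and glycogen genes 14 rose, with the branching enzyme GLC3 at 2.92 ± 0.30. Of 30 mating genes 18 rose and 5 fell, with PCL2 at 1.90 and TEC1 at 1.70. Of 108 ribosomal protein genes 102 fell, of 78 ribosome biogenesis genes 75 fell, and of 22 G2/M and M/G1 genes 13 fell and 2 rose, with KIN3 at -1.39. Adjusted over the list alone, 23 osmotic genes, 33 Msn2/Msn4 targets and 15 trehalose and glycogen genes rose, 19 mating genes rose and 5 fell, 104 ribosomal protein and 75 ribosome biogenesis genes fell, and 14 G2/M and M/G1 genes fell and 2 rose. limma called 2973 genes, 1439 up and 1534 down, of which 2941 had the same sign in replicate 1 as in replicates 2 and 3. The count was 1418 without replicate 2 and 1453 without replicate 3. Of 26 lists 12 passed camera, including every list counted here, of which the weakest was G2/M and M/G1 (adjusted p = 0.0182). None passed with an estimated correlation, where the 12 lists had an adjusted p from 0.24 to 0.609, while 3 lists had an unadjusted p under 0.05 there and 21 passed in fry. Oxidative stress defence did not pass at the preset correlation (0.0639) but did with the replicate as a block (0.0406), and its median was -0.05 in replicate 1 and 0.60 in replicates 2 and 3.

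**Figure D2:**
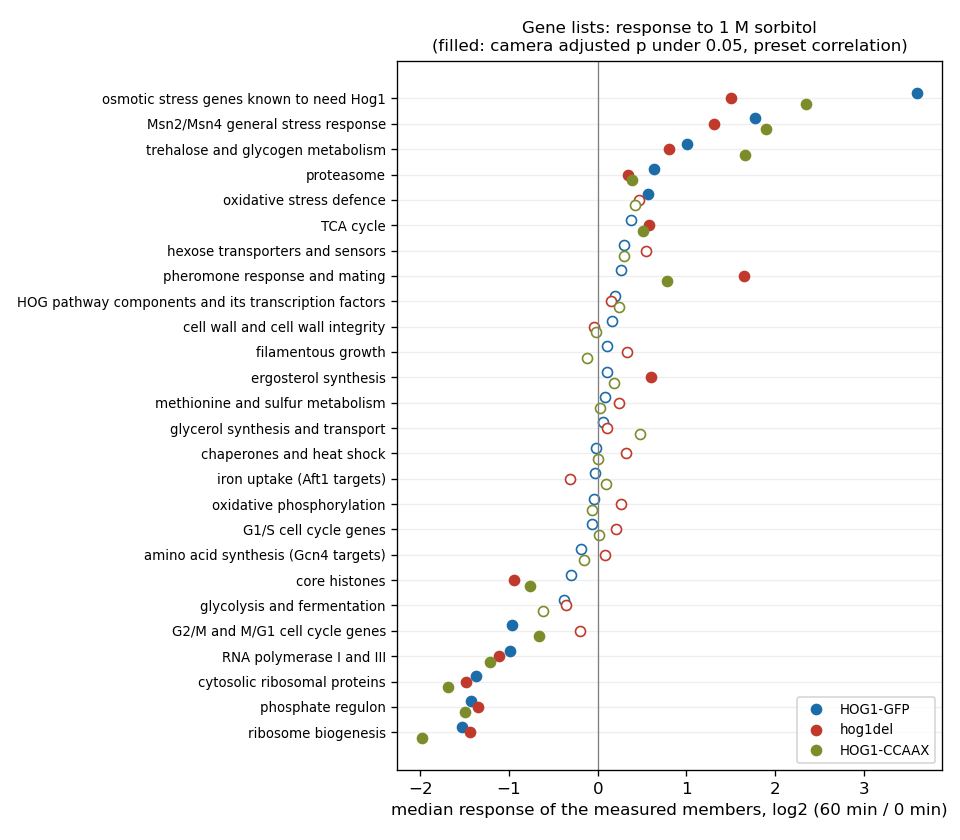
Median response to sorbitol (log2 of 60 min over 0 min, horizontal axis) of the measured members of 26 gene lists in the 3 strains. Filled points passed camera at its preset correlation, and the osmotic stress list lies at 3.60 in HOG1-GFP, 1.51 in hog1del and 2.35 in HOG1-CCAAX.

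Across all genes the mean responses were alike in shape, as a description, since genes are not independent replicates. Pearson's r was 0.847 between HOG1-GFP and hog1del, 0.928 between HOG1-GFP and HOG1-CCAAX and 0.932 between hog1del and HOG1-CCAAX, and Spearman's rho was 0.859, 0.932 and 0.931. Within single replicates the r of those pairs was 0.774 to 0.849, 0.853 to 0.913 and 0.884 to 0.932. Of the genes called in both HOG1-GFP and hog1del, 1965 of 1987 moved in the same direction.

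The next comparison was the response of hog1del, which lacks Hog1, minus that of HOG1-GFP. These strains also differ in a drug marker, as given below, so a difference need not come from Hog1. STL1 had the most negative difference (-5.29 ± 0.38), since it rose in HOG1-GFP and did not pass in hog1del. TKL2 (-4.56 ± 0.71), ALD3 (-3.83 ± 0.51), the glucose transporter HXT1 (-3.40 ± 0.33), whose family copies are uncertain, and the aldose reductase GRE3 (-2.75 ± 0.50) also responded less in hog1del. Mating and cell cycle genes responded more: TEC1 by 2.62 ± 0.21, the agglutinin subunit AGA2 by 2.50 ± 0.25, the mitotic cyclin CLB2 by 2.17 ± 0.25, KAR4 by 2.05 ± 0.29 and the mating transcription factor STE12 by 1.96 ± 0.17. CLB2 and AGA2 fell in HOG1-GFP, by 2.03 and 1.22 on the log2 scale.

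**Figure D3:**
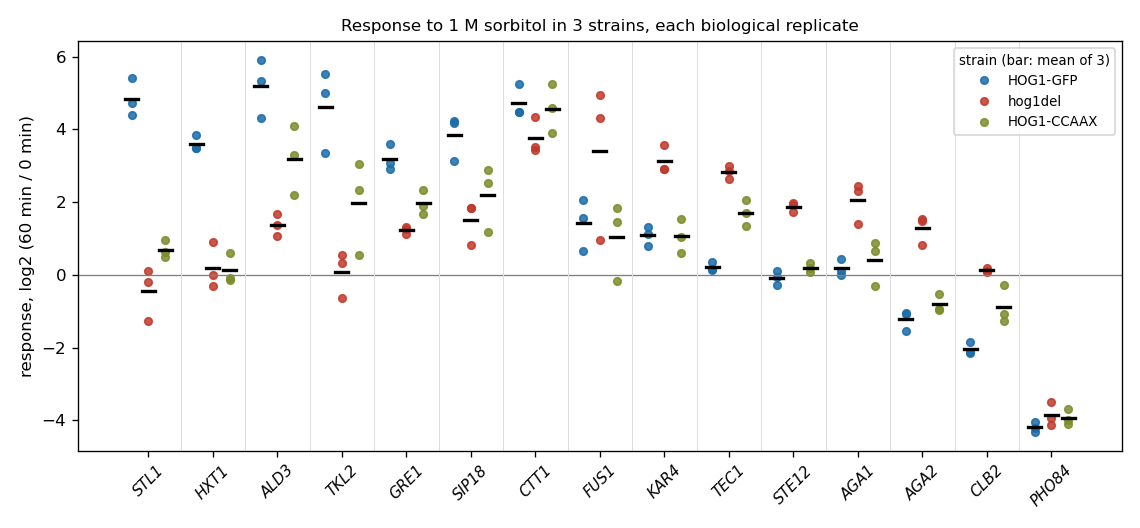
Response to 1 M sorbitol (log2 of 60 min over 0 min, vertical axis) of 15 genes in each biological replicate of the 3 strains, with bars at the means of 3. STL1 and HXT1 have mean responses of 4.85 and 3.60 in HOG1-GFP and 0.69 and 0.13 in HOG1-CCAAX, while STE12 and AGA1 are highest in hog1del, at 1.88 and 2.05.

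Of 25 osmotic stress genes, 17 responded less in hog1del and none more, with a median difference of -1.81 and GRE1 (-1.97) and SIP18 (-2.35) as examples. The osmotic list shares 12 members with the 30 genes that the authors chose on these samples, so it is not independent evidence. Of 30 mating genes, 11 responded more and 1 less, with a median difference of 0.97. AGA1 was at 1.88 ± 0.36, and FUS1 was at 1.98 ± 0.95, which did not pass (adjusted p = 0.357) but did with the replicate as a block (0.0157) and without replicate 1 (2.81, 0.00035). The exception was PRM10 (-2.97 ± 0.44), which is also one of the authors' 30 genes. Of 22 G2/M and M/G1 genes, 8 responded more and none less, with the cell separation genes DSE1 (1.63) and SCW11 (1.46). Before sorbitol limma called 0 of these 22 in hog1del, but 6 were lower and 0 higher at an unadjusted p under 0.05. Of 21 ergosterol synthesis genes 3 responded more, among them ERG11 (1.24) and ERG6 (0.80), and of 24 G1/S genes 1 did, YOX1 (1.14). Adjusted over the list alone, the counts were 22 less for the osmotic list, 20 more and 1 less for mating, 14 more for G2/M and M/G1, 4 more for ergosterol and 5 more for G1/S. With the replicate as a block, 21 osmotic genes responded less, and 23 mating genes, 16 G2/M and M/G1 genes, 7 ergosterol genes and 8 G1/S genes responded more. The hexose transporter list passed with 3 members more and 1 less, or 5 and 2 when adjusted over the list alone (camera, adjusted p = 0.0352, and adjusted p = 0.219 with an estimated correlation), and its HXT4 (2.17) and HXT2 (1.13) moved opposite to HXT1.

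limma called 149 of the 5487 genes in this difference (2.72%), 88 more and 61 less. Each of the 149 had the same sign in replicate 1 as in replicates 2 and 3, which follows largely from their call on the same replicates. With the replicate as a block the count was 805, 393 more and 412 less. In fits with no block it was 1083 without replicate 1, 2 without replicate 2 and 0 without replicate 3, where 341 genes had an unadjusted p under 0.05 in limma. With replicate 2 or 3 left out and no block, the gap between replicate 1 and the remaining replicate counts as spread. These low counts therefore do not measure the strain difference alone. Of 26 lists 12 passed camera, each with the same sign of its median in replicate 1 as in replicates 2 and 3. The lists that also passed with an estimated correlation were mating (adjusted p = 0.00645 with an estimated correlation), ergosterol synthesis (0.0207), G2/M and M/G1 (0.0233) and G1/S (0.0317), whereas the osmotic list had an adjusted p = 0.0537 with an estimated correlation. In fry 10 lists passed.

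The authors chose 30 genes for a Hog1-dependent response from the HOG1-GFP and hog1del samples, so their values in those strains are not independent evidence. The HOG1-CCAAX samples took no part in that choice as the labels state it, but the differences of HOG1-CCAAX from the other strains carry it through the values of those strains. Of the 30, 29 were measured throughout, and their median response was 2.90 in HOG1-GFP (7.46-fold), 0.74 in hog1del (1.67-fold) and 1.45 in HOG1-CCAAX (2.73-fold). All 29 exceeded 3-fold in HOG1-GFP, 0 did in hog1del and 14 did in HOG1-CCAAX. At one end, YNL194C (3.24 ± 0.36), ALD3 (3.19) and SPS100 (2.85) were among the 4 highest of the 29 in HOG1-CCAAX. At the other, HXT1 (0.13), MOR1 (-0.01) and RIB4, an enzyme of riboflavin synthesis (-0.14), stayed near 0. ALD3, SPS100, HXT1 and MOR1, and ARI1 below, were picked here after their values were seen. The mean of the 29 genes per replicate was 3.03 ± 0.12 (SD, n = 3) in HOG1-GFP, 0.63 ± 0.25 in hog1del and 1.50 ± 0.50 in HOG1-CCAAX. HOG1-CCAAX against either other strain gave p = 0.1 in a two-sided exact permutation test (adjusted p = 0.1 over 3 tests), which is the smallest that 3 against 3 allows. The test of hog1del against HOG1-GFP would restate the choice of the genes and is not used. In replicate 1 the means were 2.95, 0.34 and 0.93, and the order of strains was the same in replicates 2 and 3.

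**Figure D4:**
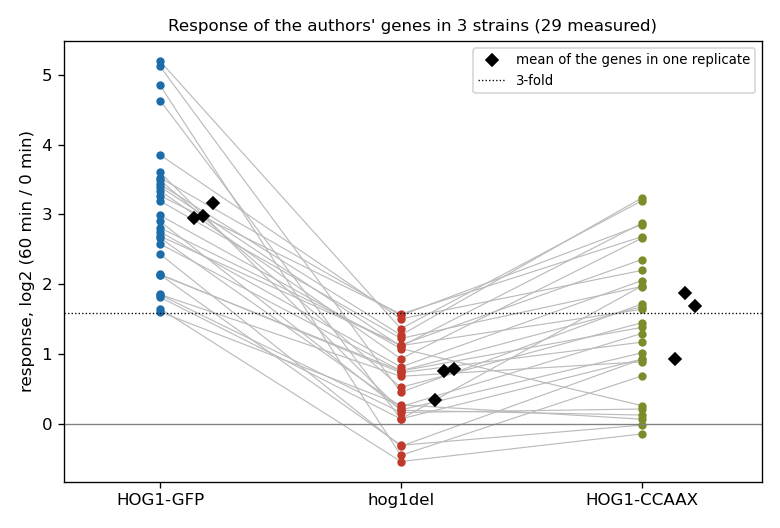
Response (log2 of 60 min over 0 min, vertical axis) of the 29 measured genes of the authors' 30 in each strain, with a line per gene. Black diamonds mark the mean of the genes in each replicate, and the dotted line marks 3-fold. The medians over the genes, which are not drawn, are 2.90, 0.74 and 1.45 in HOG1-GFP, hog1del and HOG1-CCAAX.

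Among the 29 genes, limma called 29 up in HOG1-GFP, 14 up and 1 down in hog1del and 20 up in HOG1-CCAAX. The call count in hog1del was 8 without replicate 2 and 4 without replicate 3. For the difference of hog1del from HOG1-GFP 25 were called lower, and 29 when adjusted over the list alone. The count over all genes was 2 without replicate 2 and 0 without replicate 3, where 27 had an unadjusted p under 0.05 in limma. For the difference of HOG1-CCAAX from HOG1-GFP 6 were called lower, STL1, HXT1, RIB4, NFG1, YBR116C and ARI1, and 22 when adjusted over the list alone. The count over all genes was 19 with the replicate as a block. In fits with no block it was 17 without replicate 1 and 0 without replicate 2 or replicate 3, where 24 and 18 had an unadjusted p under 0.05. For HOG1-CCAAX against hog1del 0 were called by limma, 18 had an unadjusted p under 0.05, 11 were higher in HOG1-CCAAX when adjusted over the list alone, and 8 were called higher with the replicate as a block. The count over all genes was 19 without replicate 1 and with no block, of which 18 were higher. The authors' 3-fold rule without their ranking step, above 3-fold in HOG1-GFP and below in hog1del, took 89 genes, and 46 of these exceeded 3-fold in HOG1-CCAAX. When every replicate had to meet the rule it took 28, of which 15 exceeded 3-fold in HOG1-CCAAX.

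The response of HOG1-CCAAX minus that of HOG1-GFP compared the strain with tethered Hog1 to the strain with Hog1-GFP. These strains also differ in the drug marker, so a difference need not come from the tether. STL1 (-4.16 ± 0.38), HXT1 (-3.47 ± 0.33), YBR116C (-3.40 ± 0.42), the thiamine synthesis gene THI4 (-2.79 ± 0.43) and NFG1, a regulator of filamentous growth (-2.72 ± 0.32), responded less in HOG1-CCAAX. HXT4 (2.22 ± 0.36), the glucose signalling regulator MTH1 (2.03 ± 0.26), TEC1 (1.49 ± 0.21), the cell wall mannoprotein TIR1 (1.31 ± 0.21) and the proline oxidase PUT1 (1.07 ± 0.17) responded more. SIP18 (-1.65 ± 0.49) and GRE1 (-1.22 ± 0.23) did not pass (adjusted p = 0.329 and 0.0802) but did with the replicate as a block (0.000816 and 0.0161) and without replicate 1 (0.00172 and 0.0213). CTT1 (-0.15 ± 0.39), KAR4 (-0.01 ± 0.29) and AGA1 (0.24 ± 0.36) did not pass in either fit.

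Of 25 osmotic stress genes, 2 responded less in HOG1-CCAAX, STL1 and HXT1, and none more. Adjusted over the list alone 11 responded less and 1 more, and with the replicate as a block 10 responded less. Of 30 mating genes 1, TEC1, responded more, 4 more and 1 less when adjusted over the list alone. None of 22 G2/M and M/G1 genes passed in limma over all genes and 9 had an unadjusted p under 0.05, while 7 responded more when adjusted over the list alone and 5 did with the replicate as a block. The median difference was -0.59 for the osmotic list, 0.23 for mating and 0.43 for G2/M and M/G1, and that of the osmotic list was -0.34 without replicate 1, -0.97 without replicate 2 and -0.78 without replicate 3. The glycerol list, with 1 member less and 2 when adjusted over the list alone, had a median of 0.07, a mean of -0.39 and a downward test that did not pass (adjusted p = 0.564). limma called 18 genes, 5 more and 13 less, all with the same sign in replicate 1 as in replicates 2 and 3. With quantile normalization the count was 14, of which 6 were more and 8 less. With the replicate as a block it was 167, 84 more and 83 less. In fits with no block it was 420 without replicate 1 and 0 without replicate 2 or replicate 3, where 141 and 154 genes had an unadjusted p under 0.05. There the gap between replicate 1 and the remaining replicate counts as spread. Of 26 lists 12 passed camera, among them osmotic (adjusted p = 4.09e-10), G2/M and M/G1 (7.76e-10), mating (0.00113) and trehalose and glycogen (0.000233), the last with a median of 0.58 (0.29 without replicate 2), no member called by limma over all genes or over the list alone, and 6 at an unadjusted p under 0.05. None passed with an estimated correlation, where the 12 lists had an adjusted p from 0.142 to 0.706, while 4 lists had an unadjusted p under 0.05 there. In fry 0 passed, with 6 at an unadjusted p under 0.05. The ribosomal protein and ribosome biogenesis lists passed camera at its preset correlation with medians of -0.34 and -0.46, but their medians were 0.06 and 0.03 in replicate 1 and -0.14 and -0.21 without replicate 2, and none of their members was called by limma, with 5 and 7 at an unadjusted p under 0.05. Ergosterol synthesis did not pass (0.0643) but did with the replicate as a block (0.0399).

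The response of HOG1-CCAAX minus that of hog1del compared the strain with the tethered kinase to the strain without Hog1. SPG4 (2.38 ± 0.31), the butanediol dehydrogenase relative BDH2 (1.99 ± 0.28) and FMP48 (1.81 ± 0.24) responded more in HOG1-CCAAX. AGA2 (-2.09 ± 0.25), KAR4 (-2.06 ± 0.29), STE12 (-1.68 ± 0.17), the nuclear fusion gene PRM3 (-1.42 ± 0.19) and NOP56 and NOP58, core proteins of small nucleolar particles (-1.65 ± 0.23 and -1.57 ± 0.23), responded less. STL1 was at 1.13 ± 0.38 and did not pass (adjusted p = 0.472) but did without replicate 1 (0.83, adjusted p = 0.0384).

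Of 30 mating genes, 5 responded less in HOG1-CCAAX than in hog1del and none more, with a median difference of -0.77, and 14 did so when adjusted over the list alone, with 1 more. With the replicate as a block 13 responded less and 1 more. Of 25 osmotic stress genes 1, FMP48, responded more, 15 when adjusted over the list alone and 10 with the replicate as a block, with a median difference of 1.04. Of 78 ribosome biogenesis genes 2 responded less, 3 when adjusted over the list alone, and 8 did with the replicate as a block. limma called 10 genes, 3 more and 7 less, all with the same sign in replicate 1 as in replicates 2 and 3. With quantile normalization the count was 16, 10 more and 6 less. With the replicate as a block it was 117, 58 more and 59 less. In fits with no block it was 423 without replicate 1 and 0 without replicate 2 or replicate 3, where 94 and 106 genes had an unadjusted p under 0.05. There too, the gap between replicate 1 and the remaining replicate counts as spread. Of 26 lists 16 passed camera, 15 of them with the same sign of the median in replicate 1 as in replicates 2 and 3, while the ribosomal protein list was at 0.11 in replicate 1 and -0.32 in replicates 2 and 3, and at 0.01 without replicate 2. Those that passed with an estimated correlation were mating (adjusted p = 0.0048 with an estimated correlation), ergosterol synthesis (0.0239), G1/S (0.0327) and amino acid synthesis (0.0327), the last 3 with median differences of -0.32, -0.35 and -0.31. limma called none of their members over all genes, with 7, 7 and 7 at an unadjusted p under 0.05, and 1, 0 and 2 were lower when adjusted over the list alone. The osmotic and ribosome biogenesis lists passed at the preset correlation (1.74e-17 and 3.41e-14), with an adjusted p = 0.0704 and an adjusted p = 0.372 with an estimated correlation. In fry 9 lists passed.

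Levels before sorbitol were compared between strains, to show where the strains differed from the start. In hog1del, apart from HOG1 (-3.16 ± 0.16), the pyrimidine synthesis gene URA1 (-2.04 ± 0.13), the cell wall mannoprotein CWP1 (-1.22 ± 0.22), the malate dehydrogenase MDH2 (-1.10 ± 0.14) and RIB4 (-1.01 ± 0.13) were lower than in HOG1-GFP. FIT2 and FIT3, cell wall proteins that retain iron (1.80 ± 0.20 and 1.23 ± 0.15), YLL053C (1.42 ± 0.15) and the asparaginase copy ASP3-3 (0.71 ± 0.13), which has near-identical neighbours, were higher. In HOG1-CCAAX, CWP1 was lower (-1.49 ± 0.22), and YLR159W (1.10 ± 0.15), YLR156W (1.02 ± 0.16), YLR161W (1.02 ± 0.12), the nucleotide synthesis gene IMD2 (0.91 ± 0.13) and the meiotic gene NDJ1 (0.88 ± 0.13) were higher. YLR156W, YLR159W and YLR161W lie close together, had like values and may share probes, so they need not be independent calls. STL1, AGA1 and KAR4 did not pass in either difference.

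Of 18 iron uptake genes, 2 were higher in hog1del, 4 when adjusted over the list alone, and the list passed (camera, adjusted p = 3.28e-09, and adjusted p = 0.0639 with an estimated correlation). Of 25 osmotic stress genes, CWP1 was lower in each strain, adjusted over the list alone 2 were lower in hog1del and 1 in HOG1-CCAAX, and the list medians were -0.22 in hog1del (-0.07 in replicate 1 and -0.29 without it) and -0.24 in HOG1-CCAAX (-0.03 in replicate 1, -0.40 without it and -0.11 without replicate 2), and the list passed camera in both (4.82e-06 and 1.77e-09, and adjusted p = 0.252 and adjusted p = 0.22 with an estimated correlation). limma called 15 genes in hog1del, 7 higher and 8 lower, with 58 without replicate 1, 2 without replicate 2 and 2 without replicate 3. It called 6 in HOG1-CCAAX, 5 higher and 1 lower, and 36 without replicate 1. Without replicate 2 or replicate 3 it called 0, with 55 and 46 genes at an unadjusted p under 0.05. The HOG1-CCAAX count was 3, all higher, with quantile normalization. The fit of these levels held the replicate as a block, and without it the counts were 7 and 2. All called genes had the same sign in replicate 1 as in replicates 2 and 3. Of 26 lists 12 passed camera in hog1del and 6 in HOG1-CCAAX, but the medians of 4 of the 12 and 2 of the 6 differed in sign between replicate 1 and replicates 2 and 3. None passed with an estimated correlation, with 5 and 4 lists at an unadjusted p under 0.05 there, and fry passed 1 list, iron uptake (0.0339), and 0 lists, with 5 and 1 at an unadjusted p under 0.05.

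Some osmotic genes lacked a value in at least 1 sample and were left out of the counts above. With genes measured in at least 2 of 3 replicates, the glycerol phosphatase GPP2 responded by 5.21 ± 0.18 in HOG1-GFP, 4.20 ± 0.18 in hog1del and 4.69 ± 0.18 in HOG1-CCAAX, here with n = 2. The small heat shock protein HSP12 responded by 5.41, 4.14 and 5.50. The mating gene PRM1, left out for the same reason, responded by 2.08 in HOG1-GFP, 3.22 in hog1del and 1.71 in HOG1-CCAAX. The other glycerol phosphatase GPP1 responded by 1.46 in HOG1-GFP and -0.76 in hog1del, both called by limma, and by -0.24 in HOG1-CCAAX, which did not pass. The difference of hog1del from HOG1-GFP passed for GPP1 (-2.22, adjusted p = 0.00773) and for GRE2, a reductase among the authors' 30 genes (-2.98, adjusted p = 0.00368). The glycerol-3-phosphate dehydrogenase GPD1 had values in 2 replicates of HOG1-GFP, 3.98 and 4.44, in 2 of hog1del, 3.73 and 3.06, and in 1 of HOG1-CCAAX, 4.37, and was not tested.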

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

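The tests of the pheromone genes and of the chromosome XII neighbours were chosen only after those results were seen, whereas the splits of the samples and the neighbour test were chosen before. The response to sorbitol differed between hog1del and HOG1-GFP in 149 genes, between HOG1-CCAAX and HOG1-GFP in 18, and between HOG1-CCAAX and hog1del in 10, each by a limma test of the difference itself. The 6 responses of each pair can be split in 10 ways into 3 and 3, which is too few for a share under 0.05. The real split gave 149, 18 and 10 genes and the highest other split 0 in each, so 1 of 10 splits gave as many. In the fit of the 18 samples with the replicate block, the real splits gave 3044, 3311 and 3347 genes for the responses of HOG1-GFP, hog1del and HOG1-CCAAX, and 15 and 6 for the levels before sorbitol of hog1del and HOG1-CCAAX, against a highest other of 0 each. The splits that part every replicate pair also gave 0, apart from the real ones.

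Between hog1del and HOG1-GFP, the named genes that responded more in hog1del were TEC1 (2.62), AGA2 (2.50), TIR1 (2.31), NRG2 (2.20), HXT4 (2.17), CLB2 (2.17), KAR4 (2.05), ATG41 (1.98), STE12 (1.96), AGA1 (1.88), DSE1 (1.63), SCW11 (1.46), SAM1 (1.35), ARG1 (1.28), ERG11 (1.24), YOX1 (1.14), HXT2 (1.13) and ERG6 (0.80). Those that responded less were ENA1 (-0.93), GRE1 (-1.97), RIB4 (-2.19), SIP18 (-2.35), GRE3 (-2.75), PRM10 (-2.97), HXT1 (-3.40), ALD3 (-3.83), TKL2 (-4.56), YBR116C (-4.66) and STL1 (-5.29). Between HOG1-CCAAX and HOG1-GFP they were HXT4 (2.22), MTH1 (2.03), TEC1 (1.49), TIR1 (1.31), PUT1 (1.07), RIB4 (-1.79), NFG1 (-2.72), THI4 (-2.79), YBR116C (-3.40), HXT1 (-3.47) and STL1 (-4.16). Between HOG1-CCAAX and hog1del they were SPG4 (2.38), BDH2 (1.99), FMP48 (1.81), PRM3 (-1.42), NOP58 (-1.57), NOP56 (-1.65), STE12 (-1.68), KAR4 (-2.06) and AGA2 (-2.09).

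Features outside the gene comparisons gave a signal as well. The probe for green fluorescent protein had a mean log2 ratio to the reference of 0.54 in HOG1-GFP, -5.11 in hog1del and 0.14 in HOG1-CCAAX, over replicates 2 and 3, where it was measured. The probe for the KanMX4 drug marker was at 0.87 in HOG1-GFP, -4.90 in hog1del and -5.16 in HOG1-CCAAX. The probe for green fluorescent protein thus read HOG1-CCAAX near HOG1-GFP, while KanMX4 set HOG1-GFP apart from both other strains. Differences of those strains from HOG1-GFP therefore cannot be told apart from effects of this marker or of the strain background.

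The pheromone response and mating genes responded more to sorbitol in hog1del than in HOG1-GFP, with a median difference of 0.97. The arrays of replicate 1 correlated poorly with the others, but the difference does not come from them alone, since its median was 1.05 in replicate 2 and 1.24 in replicate 3, against 0.80 in replicate 1. A lower starting level in hog1del would need the list to lie below HOG1-GFP before sorbitol by about the difference, and it lay 0.108 above. Alpha cells in the hog1del cultures would bring their markers, of which 5 of 6 rose in hog1del and 2 in HOG1-GFP, and with a median difference of 0.205 (0.102, 0.123 and 0.488 in the replicates) they cannot be told apart from the pattern, since no share of such cells is known. Before sorbitol the median of these 6 markers was only 0.096 higher in hog1del than in HOG1-GFP. limma called 0 of them there, with 0 at an unadjusted p under 0.05. A small share of alpha cells need not raise the markers visibly, so these levels do not decide. A greater response of the mating pathway in cells without Hog1 may apply as well, as a hypothesis found and tested on the same data.

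Genes whose response differed between hog1del and HOG1-GFP lay side by side more often than random genes. Of the 149 genes, 143 have a position in the reference, and among these there were 9 pairs next to each other in the order of the 5229 placed genes tested, 7 of them moving in the same direction, against a median of 4 in 10000 random sets of the same size, with a one-sided permutation p = 0.015. The 6 genes without a position were left out, among them YBR116C, whose systematic name is next to that of TKL2. Its responses in HOG1-GFP, hog1del and HOG1-CCAAX were 5.12, 0.46 and 1.72, against 4.63, 0.07 and 1.98 for TKL2. YBR116C and TKL2 may therefore not be independent signals, here and in the comparisons above. Pairs of same-family copies do not account for them, since 11.1% of the pairs, 1 pair of hexose transporters, HXT4 and HXT1, had names of the same family. Shared control of neighbouring genes may explain such pairs, as may probes that read across gene ends, and neither was tested.

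A block of 7 neighbouring genes on chromosome XII, YLR155C to YLR161W, which holds the 4 asparaginase copies, was higher in HOG1-CCAAX than in HOG1-GFP, with a median of 0.72 before sorbitol and 1.021 after it. The 10 genes around it were at -0.003 and 0.26. The arrays of replicate 1 differed from the others in feature counts and correlations, for reasons the labels do not state, but the block does not come from them alone, since its mean over replicates 2 and 3 and both times was 0.894, against a SD of 0.45. The block was chosen on the levels before sorbitol in all replicates, so only the arrays at 60 min took no part in the choice. There its median was 1.302 in replicate 2 and 1.18 in replicate 3. A different copy number of the region could give such a block and cannot be told apart from a change in the expression of these genes, since no DNA was measured and near-identical copies may share probes. The block was higher in hog1del too, by 0.63 and 1.30, and the difference of both strains from HOG1-GFP rests on the same HOG1-GFP samples. After sorbitol in hog1del, the asparaginase copies lay 1.30 to 1.37 above HOG1-GFP, but YLR156W, YLR159W and YLR161W only 0.57, 0.71 and 0.57. The latter genes were at 0.49, 0.63 and 0.55 before it, so they and the asparaginase copies moved apart in hog1del. In HOG1-CCAAX before sorbitol the asparaginase copies were at 0.47 to 0.72, and YLR156W, YLR159W and YLR161W at 1.02, 1.10 and 1.02. The members of each set may share probes, so the block may hold fewer than 7 independent signals.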

How the results depend on the processing

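The alternatives were chosen before the data were examined, except the fit of replicates 2 and 3 only with the replicate block, which was added after seeing the data. No result changed direction while called under any alternative. The values below moved by more than 1.5 times or by more than the spread between replicates, and the cause was not tested unless stated. Responses are given in the order HOG1-GFP, hog1del and HOG1-CCAAX, and differences in the order hog1del minus HOG1-GFP, HOG1-CCAAX minus HOG1-GFP and HOG1-CCAAX minus hog1del. With a 2-fold minimum, which by its construction takes fewer genes, 1070, 1228 and 1303 genes passed for the responses and 8 for the level of hog1del. Leaving out 1 replicate, which leaves fewer samples, gave 1091 to 3790, 1197 to 4005 and 1418 to 4025 for the responses, 0 to 1083, 0 to 420 and 0 to 423 for the differences, and 2 to 58 and 0 to 36 for the levels of hog1del and HOG1-CCAAX before sorbitol. In each case the highest count came without replicate 1, whose arrays correlated less with the others. The left-out fits of the responses and differences held no replicate block. Without replicate 2 or 3, the gap between replicate 1 and the remaining replicate therefore counted as spread, which can lower these counts. With replicates 2 and 3 only and the replicate block, the differences had 915, 264 and 256 genes. With the replicate block in the fit of the 9 responses they had 805, 167 and 117 genes, and all 149 genes of the first difference kept their call there. The fit of 18 samples with the group and the replicate block gave 352, 69 and 40, and without the replicate block 85 and 5 for the first and last difference. With technical replicate 1 only, where fewer genes were tested, the differences had 83, 2 and 1 genes and the level of hog1del 6. With technical replicates kept and the biological sample as a random block, the second difference had 38 genes and the levels 8 and 3. With quantile normalization the last difference had 16 genes and the levels 7 and 3. With no replicate block the levels had 7 and 2 genes, and with time 0 samples only 49 and 11.

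For the gene lists, camera with an estimated correlation passed 0, 1 and 0 lists for the responses, 4, 0 and 4 for the differences and 0 and 0 for the levels, and fry passed 19, 19 and 21, then 0 and 9 for the last 2 differences, and 1 and 0. The replicate block added oxidative stress defence to the lists of the HOG1-CCAAX response and ergosterol synthesis to those of the second difference, and leaving it out of the level fits ended the calls of 3 lists in hog1del and 2 in HOG1-CCAAX. It ended no other list call. Among the 29 measured genes of the authors' 30, leaving out 1 replicate gave 4 to 22 calls in the response of hog1del, 0 to 29, 0 to 17 and 0 to 19 in the differences and 0 to 4 in each level. The replicate block gave 19 calls for the second difference and 8 for the last. When every replicate had to meet the 3-fold rule it took 28 genes, of which 15 exceeded 3-fold in HOG1-CCAAX. Pearson's r between HOG1-GFP and hog1del was 0.888 over the genes called in HOG1-GFP. Of the other results, 152 summary values kept within these limits. Among alternatives for single genes and lists, 4033 kept direction and side of the threshold, 374 lost the call, 210 gained one and 33 values that did not pass changed sign. The number of arrays with a value limits the genes that can be tested, and 5487 genes had values in every sample. The signal over background was not measured.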

Other observations

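Markers of other yeast cell types were measured as a check on what the cultures held. Of 12 such genes, 6 rose with sorbitol in HOG1-GFP, 8 in hog1del and 6 in HOG1-CCAAX, and none fell. Among them MF(ALPHA)1 rose in hog1del (2.02 ± 0.53, with 0.10, 2.98 and 2.98 in the 3 replicates), where MF(ALPHA)2 (0.40) and SAG1 (0.31) rose too, and these 3 did not pass in HOG1-GFP or HOG1-CCAAX. Other examples are the alpha-cell receptor gene STE3, at 0.90 ± 0.26 (SE of the fit, n = 3) in HOG1-GFP, 1.06 in hog1del and 1.01 in HOG1-CCAAX, and the sporulation gene SPR3, at 1.76 ± 0.39, 2.24 and 1.77. None of the 12 differed between strains in limma, in the responses or before sorbitol. At an unadjusted p under 0.05 there were 2 in the response of hog1del minus HOG1-GFP, 1 in HOG1-CCAAX minus HOG1-GFP and 0 in HOG1-CCAAX minus hog1del, and before sorbitol 1 in hog1del and 0 in HOG1-CCAAX. With the replicate as a block, MF(ALPHA)1 (1.61, adjusted p = 0.0195), SPS4 (1.01, 0.0307) and SMK1 (0.62, 0.0158) responded more in hog1del than in HOG1-GFP. These genes were listed before the data were examined, and the examples were picked after their values were seen. Of 7 genes used as strain markers, URA3 was lower in hog1del than in HOG1-GFP before sorbitol (-0.92 ± 0.16, adjusted p = 0.0311), as URA1 was, and none of the others passed in either strain before sorbitol, with URA3 alone at an unadjusted p under 0.05 in hog1del and 0 of the 7 in HOG1-CCAAX.

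Among features that are not named as genes, 1402 had values in all 12 samples of replicates 2 and 3. In both replicates 22 of them had a log2 response above 2 and 35 one below -2 in HOG1-GFP, 36 and 35 in hog1del, and 35 and 49 in HOG1-CCAAX. They were not tested.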
